A study of Mus musculus with 11 samples.

How the data were processed

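RNA was sequenced from C57BL/6 mouse embryos made by round spermatid injection (ROSI) or intracytoplasmic sperm injection (ICSI), collected as zygotes or at the 2-cell stage. There were 11 libraries in 4 groups: 2 of ROSI zygotes and 3 each of ICSI zygotes, ROSI 2-cell embryos and ICSI 2-cell embryos. Total RNA was extracted with ISOGEN II, and stranded SMART-seq libraries were made from 1 ng of it. ROSI embryos were activated with 5 mM strontium chloride for 1 to 2 h in a calcium-free CZB medium and then kept in KSOM, and ICSI embryos were kept in KSOM. The labels give no collection times, numbers of embryos per library or batches, and do not say whether replicates with the same number in different groups belong together.

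The values are TPM as deposited by the authors, 1 column per library, and each column has the same total over all genes of the table. The authors' processing notes name fastp, Bowtie2, STAR 2.7.4a and featureCounts with genome build mm10, without their roles or order, and do not give the annotation, the strand setting or any filter. No read counts, mapping rates or duplicate rates were deposited, so none are given here.

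The table held 49585 genes, of which 186 entries shared 93 symbols, and 47096 matched 1 gene of the GENCODE M21 annotation of the same genome. Reads were recovered by scaling TPM times exon length to whole numbers, and 85.1% to 86.7% of the values per library lay within 0.01 of a whole number, where 2% would by chance. The recovered depths were 30.4 M and 85.9 M reads (M, 1e6) for the ROSI zygotes, and 83.0 M, 79.6 M and 70.7 M reads for the ICSI zygotes. They were 23.0 M, 22.7 M and 20.5 M reads for the ROSI 2-cell embryos and 8.48 M, 30.1 M and 32.9 M reads for the ICSI 2-cell embryos. For a gene of 2 kb, 3 reads correspond to between 0.0512 TPM in the deepest library and 0.396 TPM in the shallowest. Between 23409 and 31781 genes had a value above 0 per library.

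Computation used python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Genes with at least 1 TPM in at least 2 libraries were tested, 21938 in number, of which 13925 were protein-coding. TPM were used on the scale of log2(TPM + 1) without further scaling between libraries. One limma model (lmFit, contrasts.fit, eBayes with a trend) held the 4 group means of all 11 libraries, so that the groups shared 1 estimate of the spread per gene. The contrasts were ROSI against ICSI in zygotes, ROSI against ICSI in 2-cell embryos, 2-cell embryos against zygotes after ICSI and after ROSI, and the difference between these last changes. Each contrast was adjusted by Benjamini-Hochberg with a threshold of 0.05, and standard errors are those of the moderated fit.

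Before the data were examined, 22 gene lists were fixed, and a list was tested with at least 5 members among the genes tested. They were 2-cell and minor activation genes, ribosome biogenesis, spliceosome, proteasome, oocyte maternal transcripts, mRNA decay machinery, spermatid transcripts, other testis cells, cumulus cells, Polycomb, developmental regulators that Polycomb typically covers, DNA and H3K9 methylation, H3K27me3-imprinted genes, classical imprinted genes, pluripotency and early lineage, p53 targets, heat shock and integrated stress response, DNA replication and cell cycle, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded genes and replication-dependent histones. The lists were written from general knowledge and none was chosen from these libraries. Lists were tested with limma camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated, and with limma fry, adjusted over the lists of a contrast. Stage genes were those that passed and differed at least 4-fold between 2-cell embryos and zygotes in the average of ROSI and ICSI, and their overlap with the genes that differed between ROSI and ICSI was tested with the Fisher exact test.

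Genes were named by a rule fixed with the lists. In each 2-group contrast it took up to 12 genes per direction with the largest log2 difference, among those with a gene name other than a predicted or clone identifier that passed, had non-overlapping libraries and averaged at least 5 TPM in the higher group. Where fewer than 5 passed, it took the 5 smallest p-values in that direction. It added up to 4 members of each list and 18 genes followed in every contrast, and took up to 6 genes per direction for the difference of changes. A gene that this rule named in 1 list is not reported here. Gm23935 and the genes compared between libraries rich and poor in small nuclear RNA were singled out after their values were seen.

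Other settings tried were pseudocounts of 0.1 and 5, no filter on low values and a filter of 5 TPM, median-ratio scaling, quantile normalization, no trend in the variance, limma array weights, the replicate number as a block, each library left out in turn, the 2 groups of a contrast fitted alone, a 2-fold minimum, stage genes of at least 2-fold and an estimated correlation. After the data were seen, 3 were added: protein-coding genes alone with TPM rescaled over them, limma voom on the recovered reads, and zygote replicate 1 as a batch term.

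The pipeline was tested on simulated data with 100 genes changed by a log2 of 1 and 100 by 2 in each contrast. It recovered 87% and 97% of them in zygotes, 89% and 99% in 2-cell embryos, 81% and 100% between the stages after ICSI, 78% and 96% after ROSI, and 56% and 93% for the difference of changes. Unchanged genes made up 4.66%, 7.84%, 4.23%, 5.43% and 3.87% of the calls. Of the 22 lists, the 1 lowered in the simulation was called and no other, and 300 of 300 simulated stage genes were found. Simulated genes varied independently, while the estimated correlations within lists ran from 0.0432 to 0.441. The simulation could therefore not show false list calls from correlated genes. Changed genes were drawn from those with higher values, so the rates do not cover genes with few transcripts. Splice forms, alleles and transposable elements were not analysed here, since the table holds 1 value per gene.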

Results

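Gene expression was compared between mouse embryos made by round spermatid injection (ROSI) and by intracytoplasmic sperm injection (ICSI), as zygotes and as 2-cell embryos. The groups held 2 ROSI zygote, 3 ICSI zygote, 3 ROSI 2-cell and 3 ICSI 2-cell libraries, and 21938 genes were tested. Differences are on the scale of log2(TPM + 1), which understates the fold of genes with few transcripts, and each is given with its standard error (SE). The labels do not say that replicates came from separate cultures, so each p-value measures the spread between these libraries. ROSI embryos alone were activated with 5 mM strontium chloride for 1 to 2 h in another medium, so paternal cell and activation were compared together.

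Transcripts of haploid male germ cells separated ROSI from ICSI zygotes. Crisp2, which encodes a protein of the sperm acrosome and tail, averaged 11.6 TPM (SD 7.87, n = 2) after ROSI and 0.0908 TPM (SD 0.0796, n = 3) after ICSI, a log2 difference of 3.38 (SE 0.34, limma adjusted p = 0.0102). Smcp, which encodes a protein of the sperm mitochondrial capsule, averaged 13.0 TPM (SD 9.33) after ROSI and was listed at 0 in the ICSI zygotes (limma adjusted p = 0.0102). Meig1, needed for assembly of the sperm tail, averaged 28.3 TPM (SD 14.5) against 2.12 TPM (SD 0.202), a log2 difference of 3.14 (SE 0.34). Cetn1, a centrin of the germ line, was higher by 3.19 (SE 0.36), and Ldhc, the lactate dehydrogenase of germ cells, by 2.38 (SE 0.27). Tnp1, which encodes a transition protein that replaces histones in spermatids, averaged 4.66 TPM (SD 0.146) against 0.247 TPM (SD 0.179), with a limma adjusted p of 0.0207. Without ICSI replicate 3 the adjusted p was 0.0522 for Smcp, Meig1, Cetn1 and Ldhc, and without ROSI replicate 1 it was 0.0648 for Meig1 and 0.167 for Tnp1.

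Of the 42 spermatid transcripts tested in zygotes, 6 rose after ROSI over all genes tested and 25 when adjusted over the list alone, and none fell. The table held 61 genes of this list, and the rest were under the filter. Members near 0 after ICSI, such as Smcp and Crisp2, passed the filter only through ROSI libraries. They could hardly fall at either stage, which tilts the counts and list tests to higher values. The list had a median log2 difference of 1.08 (camera adjusted p = 3.75e-50, adjusted p = 0.0184 with an estimated correlation), and fry, which tests the direction of a list by itself and compares it with no other genes, gave an adjusted p of 0.00465. Protamine transcripts did not pass: Prm1 differed by 1.52 (SE 0.45) and Prm2 by 0.54 (SE 0.37). None of the 19 genes of other testis cells passed, and Sycp2, of the meiotic chromosome axis, differed by -0.46 (SE 0.15, limma adjusted p = 0.437). Sycp2, Sycp3 and Sycp1 averaged 48.7, 33.5 and 18.6 TPM in ICSI zygotes, so RNA added from testis cells could hardly show in them. The absence of passing genes therefore says little about such cells. The zygote libraries also parted by small nuclear and nucleolar RNA, with 0.473% of TPM in ROSI replicate 1 and 0.454% in ICSI replicate 1 against 1.46% to 2.36% in the others. The spermatid list differed by 1.51 between the first pair and by 0.72 among the others, and Crisp2 by 3.98 and 2.74, with 1 ROSI library on each side.

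**Figure D1:**
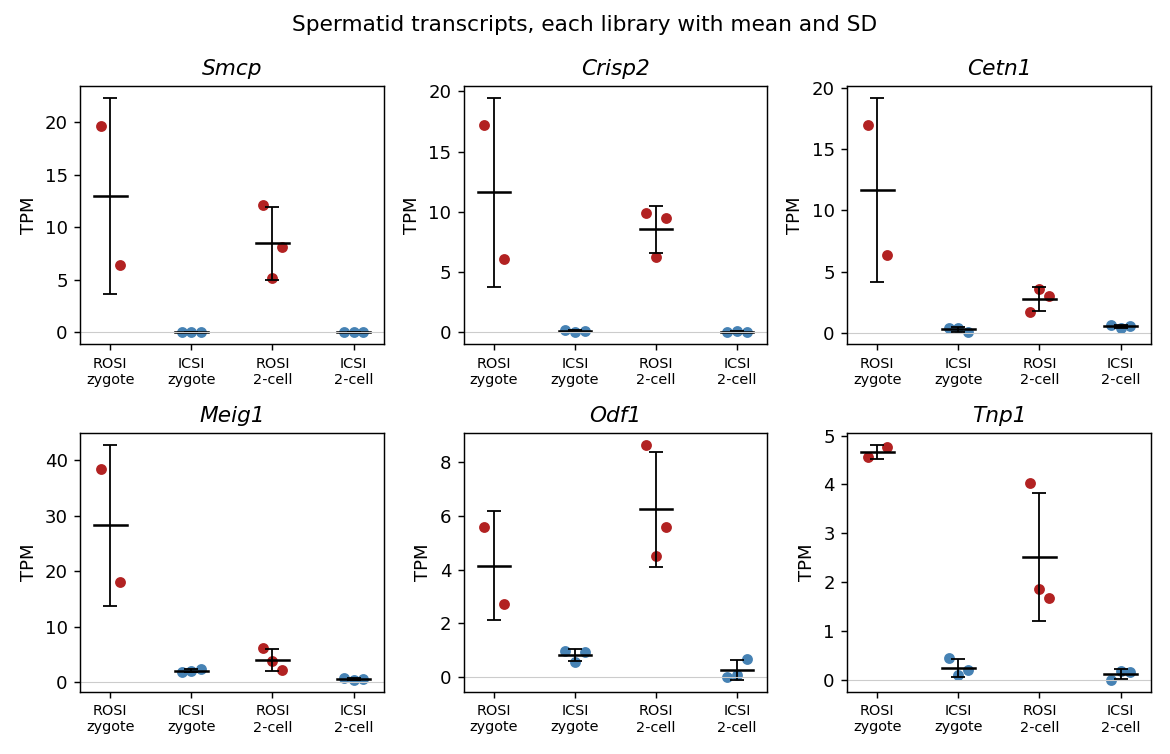
Expression of 6 spermatid transcripts (vertical axes, TPM) in each library of the 4 groups; points are libraries, horizontal lines are means and bars are SD. Crisp2 averaged 11.6 TPM in ROSI zygotes and 8.55 TPM in ROSI 2-cell embryos, against 0.0908 and 0.0304 TPM after ICSI.

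Other genes higher in ROSI zygotes included Pgam2, a phosphoglycerate mutase (log2 difference 3.09, SE 0.36), Cypt12 of a testis gene family (2.75, SE 0.38), Pabpc2, a poly(A)-binding protein of male germ cells (2.64, SE 0.38), and Dbil5, related to the acyl-CoA-binding proteins (2.54, SE 0.40). The microRNA loci Mir470 and Mir878 were higher by 3.07 (SE 0.42) and 2.79 (SE 0.41), on averages of 35 and 39 reads in ROSI zygotes. Mir7683 averaged 6.32 TPM after ROSI and was listed at 0 after ICSI, on an average of 6.5 reads. Among lower genes, Smc3, a subunit of cohesin, averaged 33.6 TPM against 73.6 TPM (log2 difference -1.10, SE 0.16, limma adjusted p = 0.0371), and Stbd1, a glycogen-binding protein, differed by -0.80 (SE 0.13, limma adjusted p = 0.0478). Susd3 (-0.80), Tmem9b (-0.88), Esyt2 (-0.80), Ndc1 (-0.67) and Igkv10-96 (-1.24) had the next smallest p-values among the lower genes and did not pass.

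Transcripts stored by the oocyte tended to lower values in ROSI zygotes, without a passing gene among the 50 tested. H1foo, the oocyte linker histone, averaged 739 TPM (SD 55.5) against 1255 TPM (SD 141), a log2 difference of -0.76 (SE 0.13, limma adjusted p = 0.0669), and was the 1 oocyte gene that passed when adjusted over the list alone. Gdf9, an oocyte growth factor, differed by -0.44 (SE 0.13) and Oosp1 by -0.66 (SE 0.18). The list median was -0.17, against -0.06 for all genes, and was -0.16 and -0.18 within the 2 kinds of zygote library (camera adjusted p = 0.000139, adjusted p = 0.995 with an estimated correlation). Ribosomal protein genes had a median of -0.15 (0 of 86 passed, 1 lower when adjusted over the list alone, camera adjusted p = 0.000707), DNA replication and cell cycle genes -0.11 (0 of 53, camera adjusted p = 0.0116) and mitochondrially encoded genes -0.34 (0 of 37, camera adjusted p = 0.0474). These 3 calls also had an adjusted p of 0.995 with an estimated correlation. By fry the adjusted p was 0.647 for each of them and for oocyte transcripts. Without ROSI replicate 1 the camera adjusted p-values were 0.0741 for oocyte transcripts, 0.778 for ribosomal proteins (median -0.05) and 0.151 for DNA replication, and without ICSI replicate 3 they were 0.279 for ribosomal proteins and 0.474 for mitochondrially encoded genes (median -0.17). The mitochondrial call also ended without ROSI replicate 2 (0.0523) and ICSI replicate 2 (0.53). Within the libraries poor in small nuclear RNA the mitochondrial median was 0.03, and among the others -0.38. The locus Gm23935, listed as a microRNA gene, took 14.1% (SD 1.16) of TPM in ROSI zygotes and 9.14% (SD 1.24) in ICSI zygotes, and protein-coding genes took 66.7% and 71.3%. TPM is a share of each library, so a larger share of this locus lowers the values of other genes. With protein-coding genes alone the median of the genes tested was 0.01, against -0.06, so part of the lower list medians may reflect these shares.

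The remaining 17 lists were not called in zygotes, and none held a gene that passed over all genes tested. Medians lay at -0.01 for 2-cell and minor activation genes, -0.11 for ribosome biogenesis, -0.07 for the spliceosome, -0.08 for the proteasome, -0.07 for mRNA decay machinery, -0.12 for cumulus cells and -0.06 for Polycomb genes. They were -0.06 for developmental regulators, -0.05 for DNA and H3K9 methylation, 0.06 for H3K27me3-imprinted genes, -0.08 for classical imprinted genes and -0.07 for pluripotency genes. The p53 targets (-0.10), stress genes (-0.09), oxidative phosphorylation genes (-0.06), replication-dependent histones (-0.07) and genes of other testis cells (-0.10) were also near the median of all genes. Oxidative phosphorylation genes were called without either ROSI replicate, with medians of 0.12 without replicate 1 and -0.28 without replicate 2. The median and the camera direction differed in sign for 2-cell genes, cumulus cells, developmental regulators, DNA and H3K9 methylation, pluripotency genes and histones. Zscan4c (0.07, SE 0.25), Duxf3 (0.43, SE 0.30), Ezh2 (-0.12), Eed (-0.19), Suz12 (-0.12), Kdm6b (-0.14) and Pou5f1 (0.03) did not pass in zygotes.

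In all, 25 genes were higher and 7 lower in ROSI zygotes (limma, Benjamini-Hochberg). An unadjusted p under 0.05 was reached by 1392 of the 21938 genes, where chance gives a share of 0.05. With array weights 149 were higher and 162 lower. Libraries of the groups did not overlap for 26.4% of genes, where chance gives 20% for 2 against 3. The count fell from 32 to 0 when the 5 zygote libraries were fitted alone (1899 genes with an unadjusted p under 0.05), and was 8 without ROSI replicate 1, 71 without ROSI replicate 2, 19 without ICSI replicate 1, 15 without ICSI replicate 2 and 4 without ICSI replicate 3. Of the 15 named genes that passed, 1, Crisp2, also passed in each of these omissions.

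At the 2-cell stage, 13 of 41 genes of early zygotic activation and 14 of 50 stored oocyte transcripts were lower in ROSI embryos, and 9 of 31 proteasome genes and 12 of 42 spermatid transcripts were higher. These 4 lists were called at the preset correlation, and each had an adjusted p of 0.532 with an estimated correlation. AF067061, a gene of the 2-cell program, averaged 16.4 TPM (SD 4.26, n = 3) after ROSI and 36.1 TPM (SD 2.43, n = 3) after ICSI, a log2 difference of -1.12 (SE 0.17, limma adjusted p = 0.00584). Nlrp4f, an oocyte gene of the NLR family, averaged 145 TPM (SD 35.6) against 311 TPM (SD 26.5), a difference of -1.12 (SE 0.15, limma adjusted p = 0.00425). Psma4, a subunit of the proteasome core, averaged 164 TPM (SD 28.0) against 80.8 TPM (SD 4.70), a difference of 1.00 (SE 0.12, limma adjusted p = 0.00361). Crisp2 averaged 8.55 TPM (SD 1.97) against 0.0304 TPM (SD 0.0527), a difference of 3.19 (SE 0.30, limma adjusted p = 0.00234).

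Of 41 genes of the 2-cell and minor activation list, 13 fell in ROSI 2-cell embryos and none rose over all genes tested, while 26 fell and 1 rose when adjusted over the list alone. Gm12794 fell by 0.99 (SE 0.16), Tcstv1 by 0.83 (SE 0.14), Tdpoz3 by 1.26 (SE 0.22) and Tcstv3 by 0.77 (SE 0.17). Zscan4c and Zscan4d, of the telomere-associated Zscan4 family, differed by -0.89 (SE 0.23, limma adjusted p = 0.0375) and -0.66 (SE 0.18, limma adjusted p = 0.0463). Without 1 library the highest limma adjusted p was 0.113 for Zscan4c, 0.136 for Zscan4d and 0.065 for Tcstv3. Zfp352 differed by -0.75 (SE 0.24, limma adjusted p = 0.0805) and Duxf3 by 0.00 (SE 0.27), neither passing. The list median was -0.64 (camera adjusted p = 1.03e-10, adjusted p = 0.532 with an estimated correlation, fry adjusted p = 0.0317). Reads shared between members of the Zscan4, Tdpoz, Usp17 and Obox families cannot be assigned to 1 member with certainty, and this holds for histone genes too.

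Of 50 oocyte transcripts, 14 fell and none rose at the 2-cell stage, and 16 fell when adjusted over the list alone. Omt2b fell by 0.82 (SE 0.10), Gdf9 by 0.69 (SE 0.12) and Nlrp9b by 0.64 (SE 0.10), while Zp3 (0.16, SE 0.13) and Mos (-0.51, SE 0.20) did not pass. The list median was -0.29 (camera adjusted p = 5.79e-10, adjusted p = 0.532 with an estimated correlation, fry adjusted p = 0.0454). Among 62 replication-dependent histone genes 4 fell (3 when adjusted over the list alone), with a median of -0.29 (camera adjusted p = 2.47e-06, adjusted p = 0.276 with an estimated correlation, fry adjusted p = 0.0211). Linker histone genes Hist1h1e and Hist1h1d fell by 1.47 (SE 0.27) and 0.58 (SE 0.11).

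**Figure D2:**
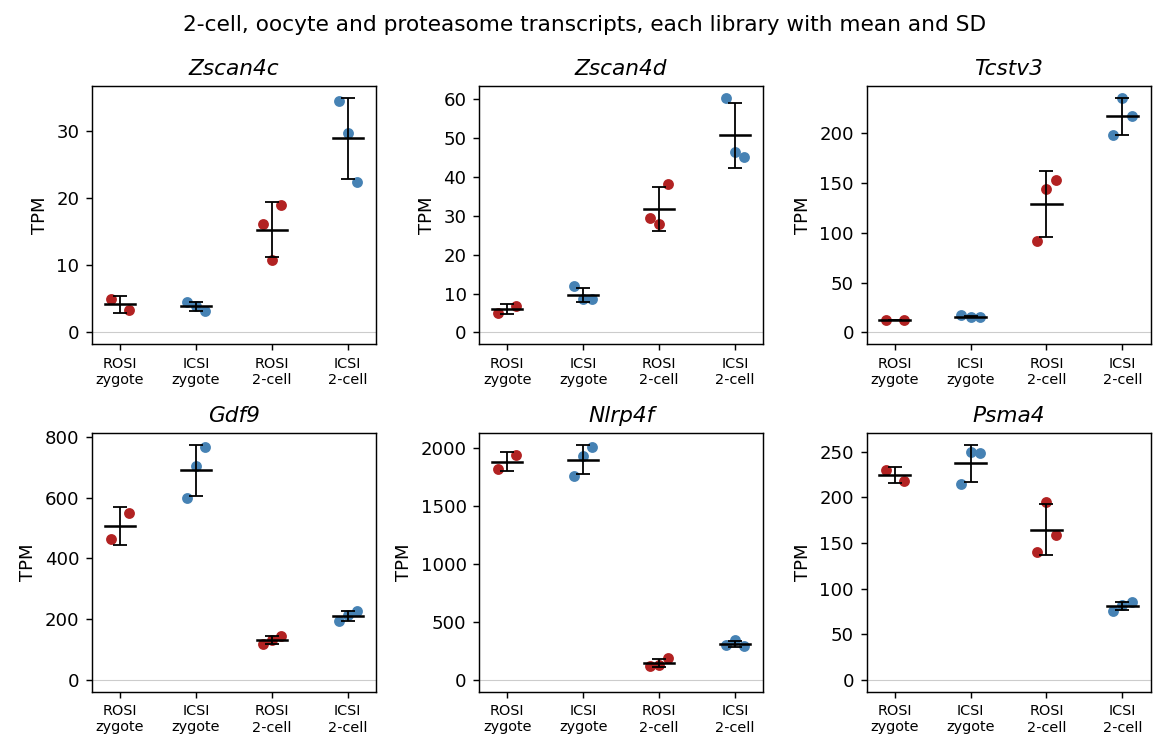
Expression of 6 genes of the 2-cell, oocyte and proteasome lists (vertical axes, TPM) in each library of the 4 groups; points are libraries, horizontal lines are means and bars are SD. In 2-cell embryos Nlrp4f averaged 145 TPM after ROSI and 311 TPM after ICSI, and Psma4 averaged 164 and 80.8 TPM.

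Proteasome genes moved the other way: 9 of 31 rose and none fell, 14 when adjusted over the list alone, with a median of 0.32 (camera adjusted p = 9.06e-07, adjusted p = 0.532 with an estimated correlation, fry adjusted p = 0.0317). Psma5 rose by 0.69 (SE 0.14) and Psmc1 by 0.67 (SE 0.14). Of 42 spermatid transcripts, 12 rose and 1 fell (16 and 1 when adjusted over the list alone), with a median of 0.46 (camera adjusted p = 1.39e-06, adjusted p = 0.532 with an estimated correlation, fry adjusted p = 0.0287). Smcp averaged 8.48 TPM (SD 3.45) after ROSI and was listed at 0 after ICSI. Odf1, of the outer dense fibres of the sperm tail, was higher by 2.54 (SE 0.29) and Tnp1 by 1.60 (SE 0.25), while Prm1 (-0.14) and Prm2 (1.06) did not pass. Among the 25 genes higher in ROSI zygotes, 12 were also higher in ROSI 2-cell embryos. Independent calls would share 1.23 (hypergeometric exact p = 5.59e-10), but both contrasts share 1 estimate of the spread per gene. Genes are not independent replicates either, so this p describes these libraries. These 12 included Smcp, Crisp2, Cetn1, Meig1, Tnp1 and Dbil5. Of 19 genes of other testis cells, Sycp3 alone rose, by 0.56 (SE 0.13).

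**Figure D3:**
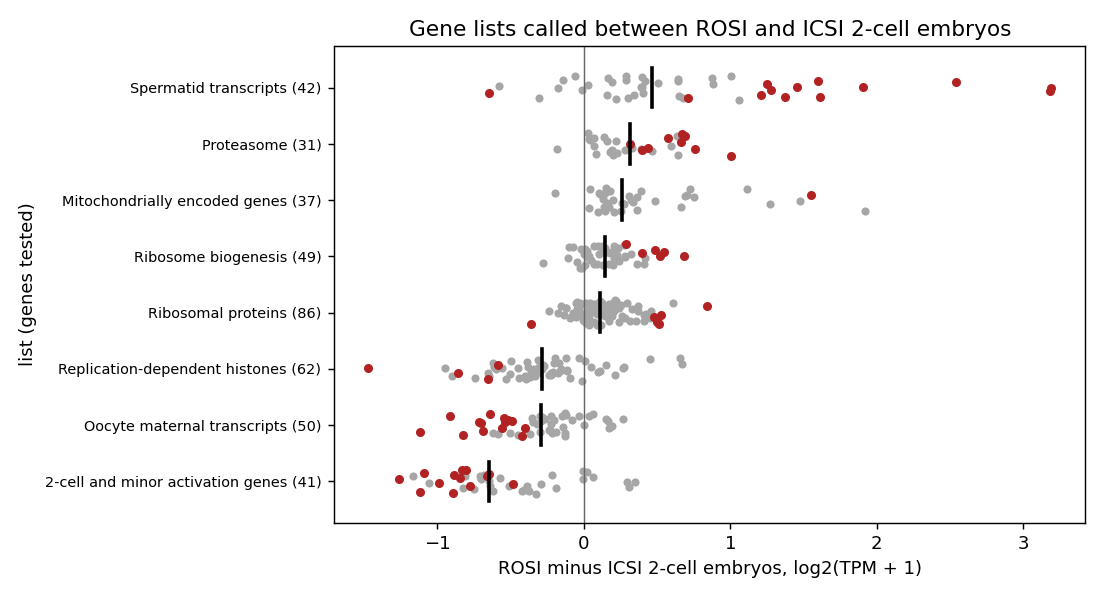
Log2(TPM + 1) difference between ROSI and ICSI 2-cell embryos (horizontal axis) for each gene of the 8 lists called there (vertical axis, with the genes tested). Points are genes, red where the adjusted p was under 0.05, and black bars are list medians, from -0.64 for 2-cell genes to 0.46 for spermatid transcripts.

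Ribosome biogenesis genes had a median of 0.14, with 6 of 49 higher (7 and 1 lower when adjusted over the list alone), among them Polr1b (0.69, SE 0.14) and Ddx21 (0.48, SE 0.11). Their camera adjusted p was 0.00342, and the adjusted p was 0.88 with an estimated correlation. Ribosomal protein genes had a median of 0.11 with 5 of 86 higher and 1 lower, the same counts when adjusted over the list alone; Rpl3 rose by 0.84 (SE 0.10) and Rplp0 fell by 0.36 (SE 0.08). Mitochondrially encoded genes had a median of 0.26 with 1 of 37 higher and 0 when adjusted over the list alone. That gene, the transfer RNA gene mt-Ts1, had 2, 1 and 1 reads after ROSI and 0 after ICSI. The camera adjusted p-values of ribosomal proteins and mitochondrially encoded genes were 0.0246 and 0.0269, against 0.88 and 0.624 with an estimated correlation. By fry the adjusted p was 0.265 for ribosome biogenesis, 0.375 for ribosomal proteins and 0.124 for mitochondrially encoded genes. Without ROSI 2-cell replicate 2 the ribosomal protein median was 0.07 (adjusted p = 0.296) and the biogenesis median 0.11 (0.0683). Without ICSI replicate 1 these medians were 0.05 (0.182) and 0.04 (0.1), and the mitochondrial median was 0.28 (0.139) without ROSI replicate 1 and 0.20 (0.236) without ICSI replicate 2.

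Genes of chromatin and imprinting lists went both ways in ROSI 2-cell embryos, and none of these lists was called. Kdm6b, an H3K27 demethylase, fell by 0.97 (SE 0.15, limma adjusted p = 0.00681) and was the 1 of 35 Polycomb genes that passed. Ezh2 (-0.24, SE 0.10), Eed (-0.25, SE 0.12) and Suz12 (-0.08, SE 0.11), the core of the complex that writes H3K27me3, did not pass. Of 11 H3K27me3-imprinted genes 2 rose (2, and 1 fell, over the list alone), Gab1 by 0.68 (SE 0.15) and Btg3 by 0.64 (SE 0.16), and without 1 library the highest limma adjusted p was 0.0681 and 0.0813. Of 24 classical imprinted genes 4 rose and 3 fell (6 and 8 when adjusted over the list alone), among them Impact, up by 1.13 (SE 0.15), and Igf2r, up by 1.09 (SE 0.16). Of 49 developmental regulators that Polycomb typically covers, 3 rose and 3 fell (4 and 4 over the list alone), with Irx5 at 0.95 (SE 0.19). DNA and H3K9 methylation genes counted 4 higher and 3 lower of 34 (5 and 5 over the list alone), with Zfp57, which guards imprints, at -0.58 (SE 0.10) and Kdm4d, an H3K9 demethylase, at 1.05 (SE 0.18). The H3K27me3-imprinted and methylation lists had medians (-0.14 and -0.01) below 0 and means (0.02 and 0.04) above it, and so did mRNA decay machinery (-0.05 and 0.01), while cumulus genes had a median of 0.01 and a mean of -0.07.

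Further lists were not called at the 2-cell stage either. Pluripotency genes counted 4 higher and 2 lower of 39, the same over the list alone, with Pou5f1 down by a log2 difference of -0.73 (SE 0.11) and Dppa5a up by 1.03 (SE 0.19). DNA replication genes counted 3 higher and 7 lower of 53 (6 and 7 when adjusted over the list alone), with Mcm4 at -1.35 (SE 0.13), Mcm3 at -0.65 (SE 0.09), Fbxo5 at -0.67 (SE 0.11) and the oocyte kinase Wee2 at -0.72 (SE 0.13). In mRNA decay machinery 4 of 36 rose and 5 fell (4 and 7 over the list alone), with Zfp36l2 at 1.20 (SE 0.19) and the decapping gene Dcp1a at -0.97 (SE 0.18). Stress genes counted 4 higher and 2 lower of 32 (5 and 2 over the list alone), with Hsp90ab1 at 0.49 (SE 0.09), and oxidative phosphorylation genes 5 and 2 of 54 (6 and 2), with Uqcrb at 1.53 (SE 0.24). Of 47 spliceosome genes 4 rose (5, and 2 fell, over the list alone), with Prpf31 at 0.54 (SE 0.09). Of 28 p53 targets 1 fell (Plk3, -0.68, SE 0.18) and 0 over the list alone, and none of 9 cumulus cell genes passed.

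Other large differences included Tufm, a mitochondrial translation factor (1.89, SE 0.21), Thy1 (1.90, SE 0.20), Ppp1r36 (1.94, SE 0.35) and Ppp1r14a (2.10, SE 0.39), each higher after ROSI. Lower genes included Il17c (-1.73, SE 0.32), the Notch target Hes1 (-1.43, SE 0.27), Duoxa2 (-1.38, SE 0.26), the gamma-secretase subunit Psenen (-1.33, SE 0.18) and Lypd3 (-1.29, SE 0.12). Several microRNA loci passed on few reads: Mir1957a, Mir224 and Mir7683 were listed at 0 after ICSI and averaged 4.33, 6.33 and 4 reads after ROSI. Mir1950 and Mir150 were listed at 0 after ROSI and averaged 6 and 4 reads after ICSI.

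In all, 1082 genes were higher and 1005 lower in ROSI than in ICSI 2-cell embryos (limma, Benjamini-Hochberg), 297 and 163 of them at least 2-fold, and 5857 had an unadjusted p under 0.05. Libraries did not overlap for 27.3% of genes, where chance gives 10%. Higher genes made up 51.8% of the calls, against 37.2% with median-ratio scaling (1197 higher, 2023 lower) and 62.4% with protein-coding genes alone (2223 higher, 1337 lower). The count of 2087 was 947 without ROSI replicate 2, 1102 without ICSI replicate 1, 1081 without ICSI replicate 2 and 597 with the 6 libraries fitted alone, and without ROSI replicate 3 the calls split into 773 higher and 1424 lower. No named gene that passed changed sign under 4 other scalings, and 53 of 92 such genes passed in every omission of 1 library.

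Genes that differed between ROSI and ICSI 2-cell embryos overlapped with those that change between the stages. Stage genes were those at least 4-fold higher (2580 genes) or lower (1881 genes) at the 2-cell stage in the average of ROSI and ICSI. Of the 1005 genes lower in ROSI 2-cell embryos, 247 (24.6%) fell between the stages, against 8.57% of all genes (odds ratio 3.85, 95% interval 3.29 to 4.49, Fisher exact p = 3.05e-55). Of the 1082 higher genes, 209 (19.3%) rose between the stages, against 11.8% of all genes (odds ratio 1.87, interval 1.59 to 2.19, Fisher exact p = 1.69e-13). The first odds ratio was 1.72 with voom, 2.30 with the stricter filter and 7.31 without a filter, and the second was 3.18 without a filter and 0.664 with a pseudocount of 0.1. Of the lower genes, 109 (10.8%) rose between the stages (odds ratio 0.909, Fisher exact p = 0.394). Of the higher genes, 42 (3.88%) fell (odds ratio 0.418, Fisher exact p = 6.71e-10). Genes that fell between the stages had a median ROSI minus ICSI difference of -0.17 and those that rose 0.12. Both contrasts share 1 estimate of the spread per gene, and genes are not independent replicates, so these p-values describe these libraries.

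Between the zygote and the 2-cell stage most genes changed after either injection. After ICSI, the homeobox gene Obox8 went from 0.764 TPM (SD 0.474, n = 3) to 370 TPM (SD 48.9, n = 3), a log2 difference of 7.75 (SE 0.19, limma adjusted p = 3.29e-10). After ROSI it went from 0.333 TPM (SD 0.108, n = 2) to 392 TPM (SD 33.9, n = 3), a log2 difference of 8.20 (SE 0.21, limma adjusted p = 8.4e-10). Rgs2, a regulator of G-protein signalling, went from 493 to 10.5 TPM after ICSI (log2 difference -5.42, SE 0.15) and from 468 to 8.80 TPM after ROSI (-5.61, SE 0.16). The homeobox gene Obox6 rose by 7.39 (SE 0.15) after ICSI and 8.03 (SE 0.17) after ROSI, and Pramel7 by 6.78 (SE 0.18) and 6.94 (SE 0.20). The phosphatase gene Alppl2 rose by 6.72 (SE 0.17) and 6.82 (SE 0.19). Pabpn1l, an oocyte poly(A)-binding protein, fell by 5.06 (SE 0.22) and 5.48 (SE 0.25), and Gspt2 by 4.84 (SE 0.13) and 5.01 (SE 0.14). Further genes among the largest changes were Selenos, Slc34a2 and Btbd18 after ICSI (7.41, 7.36 and 6.83) and Calcoco2, Trim43a and Cd63 after ROSI (7.29, 7.23 and 7.10).

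Of 41 genes of the 2-cell list, 38 rose and 2 fell after ICSI (median 4.01), and 36 rose and 2 fell after ROSI (median 3.31; 37 and 2 when adjusted over the list alone). Zfp352 rose by 4.81 (SE 0.24) after ICSI, Tcstv3 by 3.68 (SE 0.17) and Zscan4c by 2.60 (SE 0.23), while Duxf3, which is transcribed in zygotes, fell by 2.53 (SE 0.27) after ICSI and 2.97 (SE 0.30) after ROSI. Of 50 oocyte transcripts, 47 fell and 1 rose after ICSI (median -2.87) and 48 fell after ROSI (median -3.12). Ooep, of the subcortical maternal complex, fell by 4.59 (SE 0.10) and 4.42 (SE 0.12), and Gdf9 fell by 1.70 (SE 0.12) after ICSI. Proteasome genes fell more often than they rose (23 and 7 of 31 after ICSI, median -1.55; 21 and 7 after ROSI, median -0.94), with Psma7 down by a log2 difference of -4.76 (SE 0.12) after ICSI and -4.12 (SE 0.13) after ROSI. DNA replication and cell cycle genes had medians of -0.79 and -0.84, with 33 and 32 of 53 lower, while Ccne1 rose by 5.41 (SE 0.14) after ICSI.

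Histone genes rose in 52 of 62 cases after ICSI (median 1.47) and 48 after ROSI (median 1.14), with Hist2h2ac at 5.25 (SE 0.26) after ICSI. Ribosomal protein genes rose in 57 and 67 of 86 cases (medians 0.99 and 1.37), with Rpl41 at 4.08 (SE 0.13) after ICSI. Ribosome biogenesis genes rose in 29 and 33 of 49 cases (medians 0.67 and 1.06), with Nop16 at 5.61 (SE 0.17) after ICSI and 5.59 (SE 0.19) after ROSI. Of 37 mitochondrially encoded genes, 20 rose after ROSI (median 1.02, limma camera adjusted p = 0.00272, adjusted p = 0.473 with an estimated correlation) and 12 after ICSI (median 0.34, camera adjusted p = 0.0931). The difference between these changes had a median of 0.63, with an adjusted p of 0.494 with an estimated correlation and a fry adjusted p of 0.127. The camera adjusted p-values of the called lists ran from 9.38e-16 (oocyte) to 0.00796 (DNA replication) after ICSI and from 4.96e-18 (oocyte) to 0.0126 (DNA replication) after ROSI. No stage call held with an estimated correlation, where the smallest adjusted p was 0.0844 after ICSI and 0.241 after ROSI, both for histones. In zygotes the spermatid call alone held that way, and at the 2-cell stage none of the 8 calls did.

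Among further genes followed in each comparison, Ezh2 and Eed fell by 1.78 (SE 0.10) and 2.14 (SE 0.12) after ICSI, Pou5f1 by 1.06 (SE 0.11) and Kdm6b by 0.71 (SE 0.15), while Suz12 differed by 0.00 (SE 0.11). Tead4, a trophectoderm factor, rose by 4.91 (SE 0.14) after ROSI, and Dnmt1 fell by 3.33 (SE 0.12) and Zfp57 by 3.14 (SE 0.11). Zp3 differed by -0.49 (SE 0.13) after ICSI, and by 0.02 with quantile normalization and 0.04 with protein-coding genes alone. Prm2 fell by 3.21 (SE 0.33) after ICSI. Cdx2 and Xist were in the table and under the filter, with highest values of 0.7 and 1.67 TPM.

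After ICSI 7246 genes rose and 7687 fell between the stages, and after ROSI 7811 rose and 7088 fell (limma, Benjamini-Hochberg). The balance turned with the scaling: with protein-coding genes alone 6480 rose and 4936 fell after ICSI, and with quantile normalization 6638 rose and 8129 fell after ROSI. Both comparisons shared 6467 risen genes, where 2580 would be shared if the calls were independent, and 6551 fallen genes, where 2484 would be. Another 7 and 28 genes went opposite ways. Across genes, which are not independent replicates, the differences after ICSI and ROSI had a Pearson r of 0.945 and a Spearman rho of 0.93. Libraries did not overlap for 72.2% of genes after ICSI, where chance gives 10%, and 76.1% after ROSI, where it gives 20%. The median of all genes was 0.00 after ICSI, 0.20 with protein-coding genes alone and 0.15 with voom on recovered reads, and it was 0.19 after ROSI, -0.03 with quantile normalization and 0.32 with either of the other settings. TPM is a share of each library: mitochondrial ribosomal RNA took 8.01% in ICSI zygotes and 16.3% in ICSI 2-cell embryos, and protein-coding genes 71.3% and 49.3%.

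The change from zygote to 2-cell embryo differed between ROSI and ICSI for 4 genes, 3 higher and 1 lower after ROSI (limma, Benjamini-Hochberg), and 3303 genes had an unadjusted p under 0.05. Gucy2e, a guanylate cyclase of the retina, went from 3.84 to 14.4 TPM after ROSI and from 6.10 to 5.91 TPM after ICSI, a difference of changes of 1.72 (SE 0.18, limma adjusted p = 0.026), and without 1 library its adjusted p ran from 0.0246 to 0.152. Impact (1.57, SE 0.23), Rpl3 (0.99, SE 0.15), Akap1 (0.87), Gnl2 (1.24) and Isca2 (1.36) had the next smallest p-values among the higher genes and did not pass, with Impact at an adjusted p of 0.064. Among the lower genes Lypd3 (-1.17, SE 0.18), Prdx2 (-0.86), Gng3 (-0.95), Bag5 (-0.98) and Tcl1b3 (-0.90) did not pass either. The count of 4 ran from 0 to 37 when 1 library was left out, with 0 without ICSI zygote replicate 2 or 3, ROSI 2-cell replicate 2 or ICSI 2-cell replicate 2, 1 without ROSI zygote replicate 1, ICSI zygote replicate 1 or ROSI 2-cell replicate 1, 10 without ROSI zygote replicate 2 and 37 without ROSI 2-cell replicate 3. It was 244 with median-ratio scaling (64 higher, 180 lower), 627 with protein-coding genes alone and 261 with voom, and the median of all genes was 0.10, against -0.01 with median-ratio scaling.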

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

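Differences between groups were planned tests, and each test of an explanation or of another split of the libraries in this part was chosen after the result it concerns was seen.

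The ROSI minus ICSI difference changed between the zygote and the 2-cell stage for 4 genes, by the test of that difference of changes. Gucy2e is described above (1.72, limma adjusted p = 0.026). C130074G19Rik went from 0.923 to 32.6 TPM after ROSI and from 1.48 to 14.2 TPM after ICSI (1.52, SE 0.18, limma adjusted p = 0.0322). The pseudogene Gm5542 went from 0.464 to 16.6 TPM and from 0.0848 to 44.5 TPM (-1.80, SE 0.18, limma adjusted p = 0.026). The pseudogene Gm44565 went from 0.751 to 18.3 TPM and from 4.97 to 9.59 TPM (2.64, SE 0.31, limma adjusted p = 0.0322). These last 3 lay outside the rule for named genes and were chosen after their values were seen. Reads of a pseudogene can come from its relatives, which was not traced here.

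The same test of the difference of changes called 9 lists by limma camera. The median difference of changes was -0.50 for 2-cell and minor activation genes (adjusted p = 1.03e-10), -0.15 for oocyte transcripts (0.000402), -0.42 for spermatid transcripts (1.45e-05) and -0.27 for histones (1.45e-05). It was 0.43 for the proteasome (1.81e-07), 0.20 for ribosome biogenesis (8.9e-05), 0.21 for the spliceosome (0.0245), 0.27 for ribosomal proteins (1.77e-05) and 0.63 for mitochondrially encoded genes (0.000663). None held with an estimated correlation, where the smallest adjusted p was 0.366, or by fry, where it was 0.127. Without ROSI zygote replicate 1 the spermatid median was 0.03 (adjusted p = 0.216), the ribosomal protein median 0.22 (0.103) and the spliceosome median 0.16 (0.337). The spliceosome call also ended without ICSI zygote replicate 3 (0.106), ROSI 2-cell replicate 2 (0.0985) and ICSI 2-cell replicate 1 (0.195).

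Spermatid transcripts were called higher after ROSI at both stages, with 6 and 12 of 42 passing, and with an estimated correlation the adjusted p was 0.0184 in zygotes and 0.532 at the 2-cell stage. In zygotes, a shift common to the libraries poor in small nuclear RNA did not account for this. The list median was 1.02 with these libraries as a batch term (fry adjusted p = 0.00185). Such a term cannot remove a difference that varies between the 2 kinds of library. The list differed by 1.51 in the poor pair and by 0.72 among the others, with 1 ROSI library on each side. A candidate explanation is RNA carried in by the round spermatid. The test looked for its loss by the 2-cell stage, but the difference of changes of -0.42 (fry adjusted p = 0.29) became 0.03 without ROSI zygote replicate 1. At the 2-cell stage the list median was still 0.46. Carried RNA that lasts to that stage would leave no such loss, so this test cannot tell it apart from transcription in the embryo. Other testis cells carried along could not be weighed either: of 26 marker genes, 17 were under 2 TPM in ICSI zygotes, their median difference was 0.0289, and 3 reached 1 TPM after ROSI, the highest being Hsd3b6 at 2.36 TPM. The paternal cell itself and the activation by strontium stay open, untested because they go together with the groups.

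Genes that fell between the stages were over-represented among those lower in ROSI 2-cell embryos, and genes that rose among those higher. A constant factor per library did not account for this, with odds ratios of 3.30 and 1.76 under median-ratio scaling. Nor did the shallowest library, ICSI 2-cell replicate 1, with 3.97 and 1.65 without it. Such scaling cannot show whether the overlap depends on expression level. The first odds ratio was larger without a filter and smaller with the stricter filter or voom, and such a dependence was not tested. The overlap may come from ROSI embryos further into the 2-cell stage when collected, which cannot be told apart from an effect of ROSI because the labels give no collection times. The genes that rose to the 2-cell stage lay 0.0778 above the median of all genes after ROSI, while the 2-cell activation list lay below it. These libraries do not show whether that list, or any other, keeps rising or falling within the 2-cell stage. Its lower values therefore do not tell earlier from later embryos. Proteasome genes fell between the stages (medians -1.55 after ICSI and -0.94 after ROSI) but were higher in ROSI 2-cell embryos (0.32). Histone genes rose (1.47 and 1.14) but were lower there (-0.29). Oocyte transcripts, ribosome biogenesis, ribosomal proteins and mitochondrially encoded genes differed in the direction of a later stage. The second overlap also turned to an odds ratio of 0.664 with a pseudocount of 0.1.

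Splits of the 6 libraries of a contrast into 3 against 3 number 10, too few for a share under 0.05. The real split of the 2-cell libraries gave 2087 genes and 1 of the 10 splits gave as many, the highest other being 11. It gave 8 lists, and 2 of the 10 splits gave as many, the highest other being 9 for ROSI replicates 1 and 2 with ICSI replicate 1 against the rest. Stage genes among the lower and higher genes numbered 247 and 209 in the real split, the highest other being 1 for both, and 1 of the 10 splits gave as many in either case. Between the stages after ICSI 1 of the 10 splits reached the real 14933 genes, and the highest other gave 0. For all zygotes against all 2-cell embryos 100 of 462 splits were drawn. The real one, with 16453 genes, was the largest, against 1 gene at most in the others. No drawn relabelling of these libraries gave such a count, but the labels do not show that the libraries are independent. The other splits also mix the stages, which widens the spread within their groups.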

How the results depend on the processing

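Of the settings below, protein-coding genes alone, voom on recovered reads and the zygote batch term were chosen after the data were seen, and all others were planned. Over the counts and overlaps that answer a comparison, 118 values under other settings kept their direction and side of the threshold (or lay within 1.5 times the count), 24 were stronger, 30 weaker and 1 reversed. Over named genes and lists these numbers were 12560, 334, 429 and 6. A value that passed under neither setting was counted as kept even where its sign turned, and lists were judged by the camera direction. The counts between the stages stayed within 1.5 times under every setting run. The overlap of genes lower in ROSI 2-cell embryos with those that fell had an odds ratio above 1 under each setting run, from 1.72 with voom to 7.31 without a filter, against 3.85.

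Genes that differed between zygotes numbered 32, and 64 with a pseudocount of 0.1, 9 with 5, 87 without a filter, 52 with median-ratio scaling, 86 with quantile normalization, 311 with array weights, 4 with the replicate number as a block, 130 with protein-coding genes alone, 240 with voom and 0 with the zygote libraries fitted alone (limma, 1899 genes with an unadjusted p under 0.05). The 5 lists called in zygotes became 3 with the stricter filter, quantile normalization, protein-coding genes or voom, 2 with median-ratio scaling and 1 with an estimated correlation. The 2087 genes of 2-cell embryos became 1366 without a filter, 3220 with median-ratio scaling, 3263 with quantile normalization, 3560 with protein-coding genes alone, 597 with the 2-cell libraries fitted alone and 460 with a 2-fold minimum, and the 8 lists became 0 with an estimated correlation. The 4 genes whose change differed became 94 with a pseudocount of 5, 13 without a filter, 71 with the stricter filter, 244 with median-ratio scaling, 197 with quantile normalization, 220 with array weights, 0 with the replicate block, 627 with protein-coding genes, 261 with voom and 9 with the batch term. Fewer libraries leave fewer degrees of freedom in the fits of 2 groups alone; for the other settings the cause was not tested.

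Of these 7 reversed values, 5 came from other settings: the overlap of higher genes with those that rose (odds ratio 0.664 with a pseudocount of 0.1, against 1.87), Zp3 after ICSI (0.0246 with quantile normalization, 0.0358 with protein-coding genes), Zp3 after ROSI (0.31 with protein-coding genes) and mt-Rnr2 after ICSI (at 0.00, with no sign, with quantile normalization). List medians that turned sign but passed under neither setting are not among the 7. Examples are spermatid transcripts after ICSI (-0.02, and 0.67 with voom) and oxidative phosphorylation genes after ROSI (-0.17, and 0.23 with protein-coding genes). With each library left out in turn, the zygote count ran from 4 to 71, zygote lists from 3 to 9, the 2-cell count from 947 to 2197 and the count of differing changes from 0 to 37. The zygote median of oxidative phosphorylation genes ran from -0.28 to 0.12, and that of ribosomal proteins from -0.25 to -0.0531. Without ROSI replicate 1 the camera direction of both lists turned, which makes the other 2 reversed values, although the ribosomal protein median stayed below 0. Leaving out 1 ROSI zygote leaves 1, which is then taken to vary like the other groups.

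Replicate numbers did not pair the 2-cell libraries: residuals of libraries with the same number correlated at -0.01 to 0.02. In zygotes ROSI replicate 1 and ICSI replicate 1 correlated at 0.33, and ROSI replicate 2 at 0.22 and 0.21 with ICSI replicates 2 and 3. With 2 ROSI zygotes the residuals of 1 mirror those of the other. The values of ROSI replicate 2 thus follow from those of ROSI replicate 1 and are no further observation. Depth sets the floor: 3 reads on a 2 kb gene are 0.396 TPM in ICSI 2-cell replicate 1, so a 0 there says less than in the other libraries.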

Other observations

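The tests by chromosome in this part were chosen after the data were seen. Genes that were higher in ROSI 2-cell embryos were unevenly spread over the chromosomes. On chromosome 7, 130 of 1763 genes were higher (7.37%, against 4.73% elsewhere, odds ratio 1.60, 95% interval 1.32 to 1.94, Fisher exact adjusted p = 0.000159 over 40 tests). On chromosome 13, 56 of 776 genes were higher (odds ratio 1.52, Fisher exact adjusted p = 0.0427) and 50 were lower (odds ratio 1.44, Fisher exact adjusted p = 0.104). Fewer than elsewhere were higher on chromosomes 5 (52 of 1500, odds ratio 0.673) and 6 (35 of 1099, odds ratio 0.619), both with an adjusted p of 0.0427. On chromosome 11, 49 of 1683 genes were lower (odds ratio 0.599, adjusted p = 0.00544). On the X chromosome 37 of 839 genes were higher and 32 lower (odds ratios 0.882 and 0.812, adjusted p = 0.797 and 0.649), with a median difference of 0.02. Differences in expression level between chromosomes were not taken into account. Genes of 1 chromosome include families that share reads and are not independent replicates, so these p-values describe these libraries.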
